A study of Danio rerio with 4 samples.

How the data were processed

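EGFP-positive cells sorted by flow cytometry from whole zebrafish at 1, 2, 4 and 8 dpf were sequenced as 4 libraries, 1 per stage, per the labels. The samples' growth protocol names Tg(fli1ep:EGFP) fish and the study's design text names Tg(kdrl:EGFP) fish, and the difference was not settled. The samples' extraction protocol gives a 10x Chromium 3' kit of version 3, while each deposited barcode list holds 737280 barcodes of 16 bases. The submitters' processing notes name Cell Ranger 3.0.2 and Seurat 3.0 without saying what each was used for. The genome build is not given in the sources used here, and no coordinates were used.

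The deposited files hold raw UMI counts per gene and barcode, per the file headers and their whole-number values, for all barcodes and not for called cells only. Totals were 97268312, 26915937, 22614620 and 79438263 UMIs, of which 58.2%, 72.7%, 52.8% and 73.1% lay in the cells kept. The 32521 genes of the files carry 29064 symbols, and counts of genes that share a symbol were added. Green fluorescent protein is 1 of these genes. Its use, beyond the planned genes, was chosen after the data had been seen.

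Cells were called in each library on its own. A barcode was a cell where its UMIs were at least the larger of 500 and m/10, m being the 99th percentile of the 3000 largest barcodes, with at least 300 genes and at most 10% of UMIs from 13 mitochondrial genes. The minima were 4787, 3073, 1805 and 4783 UMIs, and 3254, 1819, 2367 and 4265 barcodes passed them. The gene and mitochondrial limits left 3251, 1810, 2230 and 4250, with a median mitochondrial share of 0.732%, 0.984%, 1.65% and 0.786% in the cells kept. Scrublet, as part of scanpy, marked 23, 7, 4 and 2 doublets. At 2, 4 and 8 dpf that was under 0.5% of the cells, and there the cells with the highest doublet scores were removed up to 0.8% per 1000 cells, by a rule set in advance. This removed 23, 26, 40 and 144 cells. The profile of free RNA was the sum over barcodes of 1 to 100 UMIs. In the 1 dpf library many droplets without a cell hold more, with 701 UMIs at the barcode that follows the 10000 largest and 401 far below it, so a fixed minimum of 500 UMIs takes such droplets in at that stage. The profile of 1 to 100 UMIs leaves these droplets out at 1 dpf, where it comes from 1844572 UMIs of 529214 barcodes.

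Cells of all libraries were clustered together without integration, since stage and library are the same thing here. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes without mitochondrial and ribosomal protein genes, 30 principal components, 15 neighbours and Leiden clustering of the shared-neighbour graph at resolution 1 with 10 iterations and a fixed seed were used. Endothelial-like cells were clustered again alone with the same settings. Clusters were named from marker lists written before the data were examined. A cluster took the name of a list when at least 3 of its markers had a fold of 2 or more over the mean of the other clusters and were detected in 10% or more of its cells, and the mean log2 fold was at least 0.3. Among such lists, the one with most genes among the 10 leading genes of the cluster gave the name. A cluster stayed unnamed where another class had more genes among those 10, or where its median UMIs were under 1/3 of those of the library with most of its cells and none of its own markers were among them. The 7 endothelial lists made 1 class, and subclusters could take only the names of its 6 subtypes. This rule replaced a first one, the highest mean log2 fold of 1 or more, after the names that rule gave had been seen, and the first rule is kept as an alternative. Folds of clusters use a pseudocount of 10 CPM.

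The 24 cell-type lists are endothelial, endothelial arterial, endothelial venous, endothelial lymphatic, endothelial brain barrier, endocardial, endothelial tip, hemogenic and blood progenitor, erythroid, macrophage, neutrophil, thrombocyte, neural, neural crest and pigment, cartilage and pharyngeal arch, mesenchyme and fibroblast, mural, skeletal muscle, cardiomyocyte, epidermis, liver, exocrine pancreas, gut and eye. The 25 lists of processes are cell cycle, arterial, venous, lymphatic, brain barrier, tip, endocardial, hemogenic, early endothelial transcription factors, Notch pathway, VEGF pathway, BMP and TGF-beta pathway, basement membrane and matrix, junctions, flow response, scavenger receptors and endocytosis, lipid handling, glycolysis, antigen presentation and interferon, immune and inflammatory, immediate early and heat shock, transporters, ribosomal proteins, oxidative phosphorylation and hox genes. The last 3 were made by symbol patterns, and the ribosomal pattern also takes in ribosomal protein kinase genes. Lists overlap: the subtype lists serve in both sets, and genes such as dll4, hey2, flt4, angpt2a, stab2, dab2, tal1 and lmo2 are in more than 1. Symbols absent from the files were fli1, lect2.1, acan, myocd, vmhc and try of the cell-type lists and fli1, etv6, eng, ocln, gpihbp1 and vcam1 of the others.

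Expression of the endothelial-like class was the sum of its raw counts in a library as CPM of that sum, with exact Poisson 95% intervals. Ratios were log2 with a pseudocount of 1 CPM. Their intervals are exact conditional binomial intervals of the count ratio without the pseudocount, so a ratio from very few UMIs can lie at the edge of its interval or just outside. A fold against 0 UMIs is a lower bound from a floor of 3 counts, which can lie above the bound that the exact interval gives. Comparisons were 1 to 8 dpf, 1 to 2, 2 to 4 and 4 to 8 dpf. For lists, the median ratio over members with at least 20 UMIs, the members at least 2-fold higher and lower, and the percentile of the median among 10000 random lists of the same size, matched on expression in 10 bins, were taken. This percentile describes these libraries and is no test. Shares carry exact binomial 95% intervals. The share of cycling cells was taken after thinning each cell to 1000 UMIs, as cells with UMIs of 2 or more of 12 cell cycle genes.

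Genes were named by a rule set in advance: at least 50 UMIs over both libraries, 20 CPM in at least 1, a fold of 2 or more, and a level above free RNA in the library where the gene is higher. The 12 highest and 12 lowest ratios from 1 to 8 dpf and 5 and 5 of each other comparison were named, with mitochondrial, ribosomal protein and haemoglobin genes and symbols that begin with si:, zgc:, im:, wu:, sb:, zmp:, LOC or ENSDARG or with 2 capitals and digits left out. These patterns miss longer clone names such as CABZ01073795.1, which the rule therefore named. Also named were 2 to 4 members of each list with the extreme ratios among members with at least 50 UMIs, cdh5, fli1a, kdrl and pecam1, and the 5 leading genes of each cluster described. Exceptions, chosen after their values had been seen, were GFP and the genes named under the other observations. Per-library TMM factors of edgeR were 1.08, 1.50, 0.876 and 0.705.

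Alternatives set in advance were a UMI minimum of 500 or 2000, a mitochondrial limit of 5% or 20%, no doublet removal, resolutions 0.5 and 2, each library clustered alone, an endothelial class made of all cells with UMIs of 2 or more of 10 endothelial genes, cells thinned to 1000 UMIs, subtraction of free RNA, means over cells in place of sums, a pseudocount of 10 CPM, TMM, no cells with cell cycle UMIs, list members with 100 or 1 UMIs, and thinning to 2000 UMIs. Added after the data had been seen were the first naming rule, another Leiden seed, clustering without the 2 dpf library, subtraction of a free RNA profile from barcodes beyond the 10000 largest, and the class without subclusters led by genes of other classes. These had more markers of another class than of their own subtype among their 10 leading genes, and 1 marker was enough. They were subclusters 1, 4, 7, 9, 15 and 17. Cdh5 stood at 219, 319, 419 and 527 CPM in 1, 4, 7 and 9, and lmo2 alone took out 9, so they need not be cells of another type. The share of free RNA in endothelial-like cells, estimated from haemoglobin, was 7.53%, 12.7%, 10.9% and 9.09%, or 5.57%, 14.97%, 16.8% and 15.2% with that other profile.

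Ratios, intervals and list percentiles from 1 to 8 dpf were tested on simulated data, with summed counts drawn 20 times and 200 changed genes each time among 7519. Intervals held the simulated ratio for 94.8% to 96.1% of genes. The counts were drawn from the Poisson model that the intervals assume. This coverage therefore checks the computation only, since spread between cells or libraries was not simulated. A simulated log2 ratio of 2 came out at a median of 1.92, where the changed totals and the pseudocount put it at 1.91, and one of -2 at -1.84, where they put it at -1.81. Of 200 lists without change, 8% lay outside the 5th to 95th percentile. These lists were randomly chosen genes of the last draw with independent counts, so genes that vary together were not simulated. Cell calling, clustering and naming were not tested on simulated data. Tools were Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2, scikit-learn 1.9.0 and matplotlib 3.10.9, and edgeR 4.0.16 in R 4.3.3.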

Results

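Cells carrying an EGFP reporter were sorted from whole zebrafish embryos and larvae at 1, 2, 4 and 8 days post fertilization (dpf), the first 2 stages being 24 and 48 hours. Their transcripts were counted cell by cell with droplet-based single-cell RNA sequencing. Each captured transcript carried a unique molecular identifier (UMI), so that a count is a count of molecules. The labels call the cells endothelial and set the aim as a profile of endothelial cells across these 4 stages. They name the reporter in different ways: the study's design names a kdrl promoter and the husbandry protocol a fli1a promoter, both of which are used to mark blood vessels. There was 1 library per stage and no replicate, so stage and library are the same thing here and no test was made. All intervals are exact 95% intervals that cover counting error only.

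The libraries held 97268312 UMIs at 1 dpf, 26915937 at 2 dpf, 22614620 at 4 dpf and 79438263 at 8 dpf. After droplets without a cell, low-quality cells and doublets were left out, 3228, 1784, 2190 and 4106 cells remained in the same order. Their median depth was 13822, 8350.5, 4262 and 11749 UMIs per cell, in 2293, 1613.5, 1112.5 and 1488 genes. The lowest UMI total accepted for a cell followed the depth of each library and was 4787, 3073, 1805 and 4783. Droplets without a cell held free RNA, of which haemoglobin transcripts made up 33.6% at 1 dpf against 5.96%, 0.177% and 0.814% at the later stages.

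The sorted cells were a mixture in which endothelial-like cells were the most frequent named class only at 4 dpf. At 1 dpf they made up 442 of 3228 cells, or 13.7% (12.5 to 14.9), and at 2 dpf 131 of 1784, or 7.34% (6.18 to 8.65). The share was 1167 of 2190 at 4 dpf, or 53.3% (51.2 to 55.4), and 484 of 4106 at 8 dpf, or 11.8% (10.8 to 12.8). Erythroid-like cells, defined by haemoglobin and haem synthesis genes, held 26.5% (25.0 to 28.1) of the cells at 1 dpf and 23.2% (21.3 to 25.2) at 2 dpf. The later libraries had 2.19% (1.62 to 2.90) at 4 dpf and 10.4% (9.51 to 11.4) at 8 dpf. Of the 428 such cells at 8 dpf, 418 were of cluster 11, named by 5 of 13 markers. Its mean log2 fold of the markers was 0.754, against 3.24 and 3.63 in erythroid-like clusters 0 and 10. The erythroid markers summed to 413895, 688951, 511060 and 76342 CPM in the class at the 4 stages, so the name is weaker at 8 dpf. Cartilage- and pharyngeal-arch-like cells held 47.5% (45.1 to 49.8) of the 2 dpf cells. At 1, 4 and 8 dpf they held 7.001% (6.14 to 7.94), 1.46% (1.002 to 2.06) and 0.585% (0.375 to 0.868). Epidermis-like cells held 23.04% (21.8 to 24.4) of the 8 dpf cells and 12.98% (11.8 to 14.2), 2.63% (1.94 to 3.49) and 9.36% (8.17 to 10.7) at 1, 2 and 4 dpf.

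Blood-progenitor-like and neutrophil-like cells held larger shares at each later stage, macrophage-like cells did not. Blood-progenitor-like cells, a cluster led by si:ch211-161c3.6, si:ch211-214p16.1, ascc1, spi2 and cd74a, held 0.651% (0.403 to 0.993), 3.92% (3.07 to 4.93), 9.73% (8.52 to 11.04) and 13.1% (12.1 to 14.2) of the cells at the 4 stages. That name rests on 3 of 10 markers, 1 of them among the 10 leading genes. The 10 markers summed to 1704, 1364, 824 and 249 CPM in these cells at the 4 stages. With finer clusters and with each library clustered alone the 8 dpf share was 4.92% and 6.75%. Whether blood progenitors became more frequent therefore cannot be read from these shares. Neutrophil-like cells, with the granule genes lyz, mpx and npsn, held 0.0310% (0.000784 to 0.172), 1.96% (1.37 to 2.72), 3.52% (2.78 to 4.37) and 6.14% (5.42 to 6.92). Macrophage-like cells, with marco and mfap4, had 4.40% (3.72 to 5.16), 0.673% (0.348 to 1.17), 6.48% (5.49 to 7.60) and 3.65% (3.10 to 4.27). Neural-like cells were more frequent early, with 12.5% (11.3 to 13.6) at 1 dpf and 4.37% (3.47 to 5.43), 1.51% (1.04 to 2.11) and 1.80% (1.42 to 2.26) later. Mesenchyme-like cells held 0.155% (0.0503 to 0.361) and 0.168% (0.0347 to 0.491) early and 4.79% (3.94 to 5.77) and 6.23% (5.51 to 7.02) at 4 and 8 dpf. Their name rests on 7 of 10 markers, none of them among the 10 leading genes. The 10 markers summed to 6727 CPM in these cells at 4 dpf and 924 at 8 dpf, so the name is weaker at 8 dpf. Skeletal-muscle-like cells made up 2.51%, 0.280%, 0.457% and 0.536% of the libraries. Gut-like cells made up 1.24%, 0%, 0.731% and 0.487%, and mural-like cells 0.365% and 1.44% at 4 and 8 dpf. No gut-like cell was seen at 2 dpf, where a count of 0 allows up to 0.207%, and no mural-like cell at 1 or 2 dpf, where it allows up to 0.114% and 0.207%. Liver-like and exocrine-pancreas-like clusters each held under 1% of every library.

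**Figure D1:**
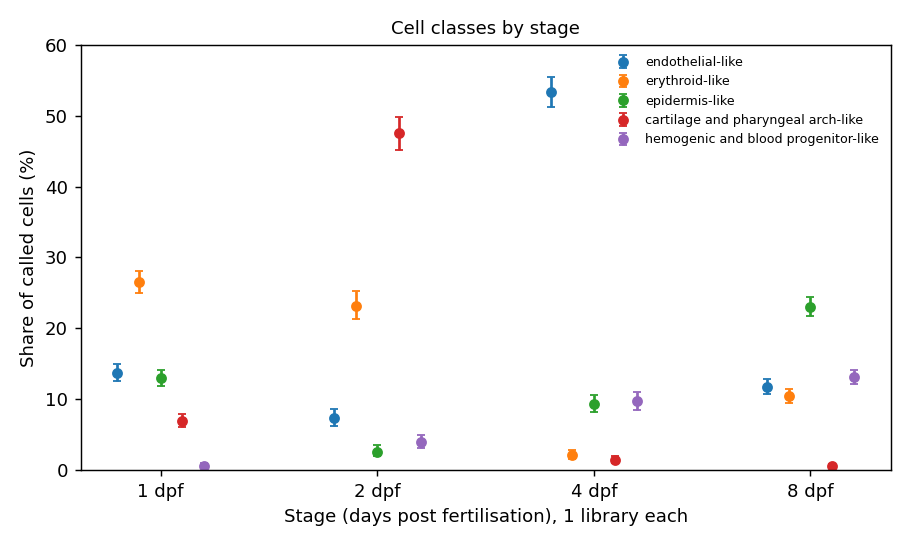
Share of the cells of each library, in percent, in the endothelial-like, erythroid-like, epidermis-like, arch-like and blood-progenitor-like classes at 1, 2, 4 and 8 dpf. Bars are exact 95% intervals of counting error. The endothelial-like share was 53.3% at 4 dpf and at most 13.7% at the other stages, and the arch-like share was 47.5% at 2 dpf.

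The EGFP sort and the UMI minimum can both set these shares. With a minimum of 500 UMIs in every library the erythroid-like share at 1 dpf was 47.8% and the endothelial-like share at 8 dpf 18.5%. When any cell with UMIs of 2 of 10 endothelial genes was taken as endothelial the 2 dpf share was 16.9%. The arch-like share at 2 dpf was 31.4% with finer clusters, 17.1% with each library clustered alone and 25.2% under the naming rule that was tried first. The same 3 settings gave 22.5%, 15.9% and 4.85% for epidermis-like cells at 8 dpf, and 4.92%, 6.75% and 13.1% for blood-progenitor-like cells at 8 dpf. Unnamed clusters held 18.4% (17.05 to 19.8), 7.90% (6.69 to 9.25), 5.25% (4.35 to 6.27) and 19.97% (18.8 to 21.2) of the cells. The largest of them, cluster 4 with 465 cells at 1 dpf and 133 at 2 dpf, was led by foxa2, cxcl12b, si:dkey-43p13.5, pax1b and nanos1. The next, cluster 6 with 509 cells at 8 dpf, was led by si:rp71-77l1.1, zgc:153911, foxq1a, mmp30 and si:ch1073-303k11.2.

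The endothelial-like class consisted of 5 of the 36 clusters, and different clusters supplied it at different stages. At 1 dpf it came from cluster 13, with 398 cells led by esm1, dab2, stab2, CABZ01075125.1 and rab11bb. Cluster 31 supplied 43 cells led by slc29a1b, spock3, hapln1b, si:ch211-145b13.6 and adcy2b, and cluster 2 supplied 1 cell. At 8 dpf it came from cluster 2, with 240 cells led by plvapb, plvapa, rgs5b, cd81b and cx43. Another part was from cluster 12, with 169 cells led by lyve1a, cldn11a, lyve1b, angpt2a and myct1a among others, and the rest from cluster 8, with 75 cells led by clic2, mb, krt94, errfi1a and fabp11a. The 4 dpf library shared these 3 clusters, with 458, 258 and 447 cells. The 2 dpf library had 73 cells in cluster 2, 24 in cluster 13, 22 in cluster 8, 8 in cluster 12 and 4 in cluster 31. All values below compare the summed counts of the whole class in each library, scaled to the same total and given as CPM.

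Genes that define the endothelium were present at all 4 stages and above their level in free RNA. The adhesion gene cdh5 (VE-cadherin, ENSDARG00000075549) had 469 (449.8 to 489.7) CPM at 1 dpf, 538 (494 to 584) at 2 dpf, 231 (218 to 244) at 4 dpf and 165 (154 to 177) at 8 dpf. Droplets without a cell held 23.9, 20.3, 117 and 18.8 CPM of it. The transcription factor gene fli1a (ENSDARG00000054632) had 365 (347 to 383), 369 (334 to 408), 333 (318 to 349) and 144 (134 to 156) CPM. The VEGF receptor gene kdrl (ENSDARG00000105215) had 231 (217 to 245), 164 (141 to 191), 136 (126 to 146) and 129.6 (119 to 140.3), and the adhesion gene pecam1 (ENSDARG00000060263) had 183 (171 to 196), 199 (173 to 228), 124 (114 to 134) and 135 (125 to 146). From 1 to 8 dpf the log2 ratios were -1.50 (-1.63 to -1.39) for cdh5, -1.33 (-1.47 to -1.21) for fli1a, -0.83 (-0.98 to -0.69) for kdrl and -0.44 (-0.59 to -0.29) for pecam1. With the TMM scaling of edgeR in place of CPM these ratios were -0.89, -0.72, -0.22 and 0.17, so that the direction of pecam1 depended on the scaling. The direction between neighbouring stages also turned with TMM for cdh5 from 1 to 2 dpf (0.20 against -0.28), for fli1a from 1 to 2 dpf (0.02 against -0.45) and from 2 to 4 dpf (-0.15 against 0.62). It turned too for kdrl from 2 to 4 dpf (-0.28 against 0.49) and from 4 to 8 dpf (-0.07 against 0.25), and for pecam1 from 1 to 2 dpf (0.12 against -0.35) and from 2 to 4 dpf (-0.68 against 0.09).

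Transcripts of green fluorescent protein, the marker of the sort, were counted as a gene of their own, GFP_gname, which was chosen after its values were seen. In the endothelial-like class they stood at 4403 (4343 to 4464) CPM at 1 dpf, 468 (428 to 512) at 2 dpf, 2784 (2739 to 2829) at 4 dpf and 561 (540.0 to 583) at 8 dpf. Droplets without a cell held 264, 276, 528 and 41.2 CPM. A GFP UMI was found in 74.2%, 29.01%, 74.04% and 51.03% of these cells at median depths of 9273, 6670, 3816 and 7834 UMIs. In neural-like cells, where the marker should be absent, it was found in 15.2%, 17.9%, 6.06% and 2.70% at 9712, 5170.5, 4237 and 9289.5 UMIs. At 2 dpf the arch-like class had more GFP, 953 (929 to 978) CPM, than the endothelial-like class. At 1 dpf it had 807 (775 to 840.2). Erythroid-like cells had 20.2, 8.26, 28.6 and 5.37 CPM of GFP and epidermis-like cells 32.8, 10.9, 189 and 11.9, all below the droplets without a cell.

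Ratios between 1 and 8 dpf in the endothelial-like class carry a pseudocount of 1 CPM, which sets their order where a library has few UMIs of a gene. At 8 dpf the interferon-induced antiviral gene rsad2 (ENSDARG00000004952) had 242 (228 to 256) CPM against 1 UMI at 1 dpf, a log2 ratio of 7.64 (7.63 to 15.42). Plvapa (ENSDARG00000076972), which encodes a protein of the diaphragms of fenestrated vessels, had 194 (182 to 207) CPM against no UMI, at least 297-fold higher. The lymphatic marker lyve1a had 649.5 (627 to 673) CPM, with a ratio of 6.17 (5.87 to 6.84). Lin28a (ENSDARG00000016999), an RNA-binding regulator of early development, had 76.9 (69.1 to 85.4) CPM at 1 dpf and no UMI at 8 dpf, at least 121-fold lower. F13a1b (ENSDARG00000036893), for a subunit of coagulation factor XIII, went from 743 (719 to 769) CPM to 2.97 (1.63 to 4.99), a log2 ratio of -7.55 (-8.84 to -7.22). The 1 dpf values come from clusters 13 and 31 and 1 cell of cluster 2, and the 8 dpf values from clusters 2, 8 and 12.

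Among the other 8 dpf genes, the angiopoietin gene angpt2a had a log2 ratio of 7.08 (6.94 to 11.84) with 2 UMIs at 1 dpf, the G-protein regulator rgs5a 7.47 (7.46 to 15.25) with 1 UMI, and lpin1, for an enzyme of triglyceride synthesis, 7.04 (6.77 to 10.01). Rgs5a, lpin1 and plvapa are among the 10 leading genes of subcluster 15, with 34 cells at 8 dpf, together with the mural genes pdgfrb and ndufa4l2a. Without subclusters led by genes of other classes the ratios of rgs5a, lpin1 and plvapa were 4.97, 6.56 and 6.86. Loxl1, of the lysyl oxidase family that crosslinks elastin, was at least 157-fold higher, the claudin gene cldn11a at least 156-fold and CABZ01073795.1 at least 159.6-fold, each with no UMI at 1 dpf. The chaperone genes hsp90aa1.2, hsp70.2 and hsp70.1 had ratios of 6.72 (6.52 to 7.05), 6.51 (6.30 to 6.83) and 6.36 (6.06 to 6.999). The free RNA held more of them in the older library too, 85.7 against 631 CPM for hsp90aa1.2, 67.2 against 1441 for hsp70.2 and 22.8 against 371 for hsp70.1. Counts of the near-identical hsp70 copies are uncertain where reads could fall on more than 1 of them.

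Among the other 1 dpf genes, the nucleoside transporter gene slc29a1b had a ratio of -6.75 (-14.56 to -6.77) with 1 UMI at 8 dpf, the kinase substrate gene marcksb -6.58 (-9.57 to -6.33), the linker histone gene h1f0 -5.71 (-6.76 to -5.38) and tmem119b -5.46 (-7.73 to -5.15). The microfibril gene mfap2 was at -5.44 (-7.17 to -5.10) and the Hairy-related repressor gene her2 at -5.25 (-6.60 to -4.90). Genes of cell division completed the group: ube2c at -5.35 (-6.64 to -5.01), cks1b at -5.31 (-6.82 to -4.96), kpna2 at -5.20 (-8.18 to -4.93) and the histone gene hist1h4l at -5.39 (-6.06 to -5.09). Counts of hist1h4l, a symbol of many near-identical copies, and of ube2c, a symbol of 2, were added and are uncertain in how reads were shared. Over all 9529 genes measured, the median log2 ratio from 1 to 8 dpf was -0.62, and -0.08 with TMM. Gene lists are therefore given with their median and with that median relative to all genes. Members given as the extremes of a list are those among members with at least 50 UMIs over both libraries. Members with small negative ratios, such as stab1, ldhba, nrp1a, edn1, ednraa and afdna below, turn positive with TMM.

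Cell division genes were lower at 8 dpf throughout. All 38 measured cell cycle genes were at least 2-fold lower, with a median log2 ratio of -3.94, or -3.31 relative to all genes. With the members at 0 set to their bound it was -4.01, and it lay below all of 10000 random lists of like expression. Their ratios ran from -5.98 (-7.16 to -5.65) for the ribonucleotide reductase gene rrm2 and -5.43 (-7.48 to -5.11) for the mitotic kinase gene aurkb to -2.07 (-2.25 to -1.93) for the replication clamp gene pcna and -1.82 (-2.86 to -1.32) for uhrf1. In 28 of the 38 the endothelial-like level at 1 dpf was at or below that in free RNA, 277 against 784 CPM for rrm2. Positional identity genes of the hox clusters were lower in 22 of 24 by 2-fold or more, with a median of -2.62 (-1.99 relative), again below all random lists. They ran from -3.84 (-6.10 to -3.47) for hoxa9b to -0.65 (-1.30 to -0.13) for hoxa3a. With a pseudocount of 10 CPM in place of 1 the medians were -2.102 for the cell cycle list and -0.95 for the hox genes, many of which have under 10 CPM. With every hox gene of 1 or more UMIs the median was -1.66.

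Interferon and inflammatory genes were higher at 8 dpf. Of 19 antigen presentation and interferon genes, 17 were at least 2-fold higher, with a median of 3.76 (4.38 relative), above all random lists. The median was 3.95 with members at 0 at their bound and 1.39 with a pseudocount of 10 CPM. The ubiquitin-like gene isg15 had 829 CPM against 13.1, a ratio of 5.88 (5.62 to 6.38), while the interferon-regulatory gene irf9 was at -0.94 (-1.41 to -0.57). Of 19 immune and inflammatory genes, 14 were at least 2-fold higher (median 2.03, 2.65 relative, above all random lists). The NF-kappaB inhibitor gene nfkbiaa was at 4.23 (4.01 to 4.58), the chemokine gene cxcl8b.1 at 4.01 (3.62 to 5.60) and the adhesion gene sele at 0.07 (-0.04 to 0.19). In the older library, 10 of the 19 were no higher in the class than in free RNA, among them nfkbiaa with 467 against 979 CPM. Immediate early and heat shock genes were at least 2-fold higher in 17 of 23 (median 2.09, 2.71 relative, above all random lists). They ran from 0.06 (-0.02 to 0.14) for btg2 and 0.16 (0.09 to 0.22) for ier2a to the hsp70 genes above, and 2 of them were no higher than in free RNA.

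Metabolic genes differed in direction. Glycolysis genes were at least 2-fold higher at 8 dpf in 9 of 17 (median 1.19, 1.82 relative, percentile 99.98 of random lists). The list was led by pkma for pyruvate kinase at 3.27 (3.01 to 3.70) and eno1a for enolase at 3.26 (3.001 to 3.68). Lowest, aldoaa was at 0.04 (-0.05 to 0.12) and ldhba at -0.17 (-0.40 to 0.04), with 6 of the 17 no higher than in free RNA. Oxidative phosphorylation genes were at least 2-fold lower in 49 of 86 and higher in 3 (median -1.10, -0.48 relative, percentile 0.160). Those with at least 50 UMIs ran from -2.91 (-3.55 to -2.57) for ndufa10 and -2.72 (-2.97 to -2.54) for atp5mc1 to 0.86 (0.44 to 1.40) for uqcrb and 1.35 (0.78 to 2.38) for cox8b. Of all 86, 42 were no higher than in free RNA. Ribosomal protein genes had a median of 0.41 (1.03 relative, percentile 99.97) with 9 at least 2-fold higher and 4 lower of 87, 52 of them no higher than in free RNA. The symbol pattern that made this list also took in kinases and a binding protein that are not ribosomal. These held 3 of its 4 extremes, rps19bp1 at -1.80 (-2.44 to -1.41), rps6ka3a at -1.79 (-2.47 to -1.38) and rps6ka3b at 1.66 (1.24 to 2.33), beside rpl26 at 4.54 (4.23 to 5.22). Lipid handling genes had 3 higher and 6 lower of 9 (median -1.17, -0.54 relative, percentile 8.94). The lipoprotein lipase gene lpl was at 4.47 (4.22 to 4.89) and the fatty acid binding gene fabp11a at 2.07 (1.97 to 2.19) against apoc1 at -4.03 (-4.66 to -3.73) and apoeb at -2.07 (-2.28 to -1.90). Transporter genes had 5 higher and 4 lower of 11 (median 0.74, 1.37 relative, percentile 99.2). They ran from slc22a7b.1 at -3.96 (-4.75 to -3.62) and slc3a2a at -2.83 (-3.55 to -2.47) to mfsd2ab at 1.87 (1.56 to 2.30) and slc3a2b at 1.94 (1.46 to 2.91).

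Markers of vessel identity were split. Lymphatic markers were higher in 3 of 6 by 2-fold or more (median 0.93, 1.55 relative, percentile 97.97), among them lyve1a and angpt2a. In contrast, lyve1b was at -0.68 (-0.84 to -0.52) and mrc1a at -1.69 (-2.43 to -1.25). Venous markers were lower in 6 of 8 (median -1.53, -0.91 relative, percentile 4.68). The endocytic adaptor gene dab2 was at -3.15 (-3.36 to -2.99), the scavenger receptor genes stab2 at -2.56 (-2.81 to -2.38) and stab1 at -0.40 (-0.68 to -0.13), and ephb4a at 1.04 (0.55 to 1.76). Arterial markers had 1 higher and 2 lower of 8, with a median of -0.43 (0.19 relative, percentile 52.4) that turned to 0.18 with TMM. They ran from hey2 at -3.02 (-3.36 to -2.78) and gja5a at -1.96 (-3.37 to -1.42) to dlc at 0.38 (0.07 to 0.72) and notch1b at 1.42 (1.04 to 1.97). Only 2 of the 10 brain barrier markers were measured (median -1.21, -0.59 relative, percentile 28.5), among them the claudin gene cldn5a at -0.61 (-0.81 to -0.42). Tip cell markers went both ways, with esm1 at -3.43 (-3.56 to -3.32) and mcamb at -1.95 (-2.21 to -1.75) against pfkfb3 at 2.22 (1.94 to 2.64) and angpt2a. Their median was 0.05 (0.67 relative, percentile 79.5), with 2 higher and 2 lower of 5. Endocardial markers had 2 higher and 1 lower of 6 (median 0.08, 0.70 relative, percentile 78.6). Those with at least 50 UMIs ran from tmem88a at -1.94 (-2.04 to -1.85) and tmem88b at 0.11 (-0.04 to 0.25) to hand2 at 1.37 (0.94 to 2.01) and the flow-induced gene klf2a at 2.09 (1.94 to 2.26).

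Transcription factor genes of early blood and vessel development were lower at 8 dpf. Hemogenic genes were at least 2-fold lower in 5 of 6 (median -2.19, -1.57 relative, percentile 0.220). Spi2 was at -3.07 (-5.09 to -2.64), tal1 at -2.66 (-3.05 to -2.40), lmo2 at -2.56 (-2.72 to -2.43) and cebpa at -1.82 (-2.49 to -1.42). Early endothelial transcription factor genes, a list that shares tal1, lmo2 and gata2b with the hemogenic one, were lower in 7 of 12 and higher in 1 (median -1.23, -0.60 relative, percentile 7.20). Examples are fli1b at -3.45 (-3.95 to -3.17), sox7 at -0.71 (-0.78 to -0.63) and ets2 at 1.27 (1.07 to 1.50). Notch pathway genes had 3 higher and 8 lower of 17 and a median of -0.66, -0.04 relative to all genes (percentile 41.98). They ran from her15.1 at -3.42 (-3.63 to -3.27) and hey2 to notch1b and her6 at 2.25 (2.18 to 2.32). VEGF pathway genes had 0 higher and 5 lower of 11 (median -0.94, -0.32 relative, percentile 28.02). The co-receptor genes nrp2b, nrp2a and nrp1a were at -2.78 (-3.59 to -2.40), -2.21 (-3.04 to -1.79) and -0.40 (-0.83 to 0.00).

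The remaining lists lay near the median of all genes, apart from the flow response. Flow response genes were at least 2-fold higher in 4 of 10 and lower in 0 (median 0.75, 1.37 relative, percentile 98.01). Klf2a was highest, its paralogue klf2b was at 1.97 (1.81 to 2.17), edn1 at -0.16 (-0.62 to 0.28) and ednraa at -0.17 (-0.30 to -0.04). BMP and TGF-beta pathway genes had 2 higher and 8 lower of 20 and a median of -0.31 (0.31 relative, percentile 78.9) that turned to 0.26 with TMM. Their extremes were smad5 at -2.40 (-2.78 to -2.14) and id3 at -1.73 (-1.83 to -1.64), and bmpr2a at 1.05 (0.77 to 1.40) and id2b at 1.68 (1.38 to 2.104). Junction genes had 1 higher and 5 lower of 16 and a median of -0.59 (0.03 relative, percentile 44.2) that turned to 0.01 with TMM. Among members with at least 50 UMIs, cgnl1 at -2.18 (-2.47 to -1.97) and cdh5 were lowest, afdna at -0.09 (-0.29 to 0.12) and f11r.1 at 1.0003 (0.42 to 1.87) highest. Basement membrane and matrix genes had 3 higher and 8 lower of 18 (median -0.76, -0.14 relative, percentile 40.8). The range was from nid2a at -3.82 (-6.78 to -3.49) and sparc at -2.66 (-2.91 to -2.46) to fn1b at 1.25 (0.68 to 2.19) and nid1a at 1.40 (0.80 to 2.55). Scavenger receptor and endocytosis genes had 1 higher and 6 lower of 14 (median -0.69, -0.06 relative, percentile 35.1). With dab2 and stab2 lowest, the highest were the cathepsin gene ctsla at 0.42 (0.37 to 0.47) and asah1b at 1.64 (1.23 to 2.28). Members no higher than in free RNA numbered 5 in the matrix list, 3 in the junction list, 2 in the BMP and TGF-beta list, and 2 in the scavenger list. There were 3 in the transporter list, 2 in the lipid list, 4 in the hox list, 2 in the interferon list and 1 each in the hemogenic, early transcription factor and VEGF lists.

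**Figure D2:**
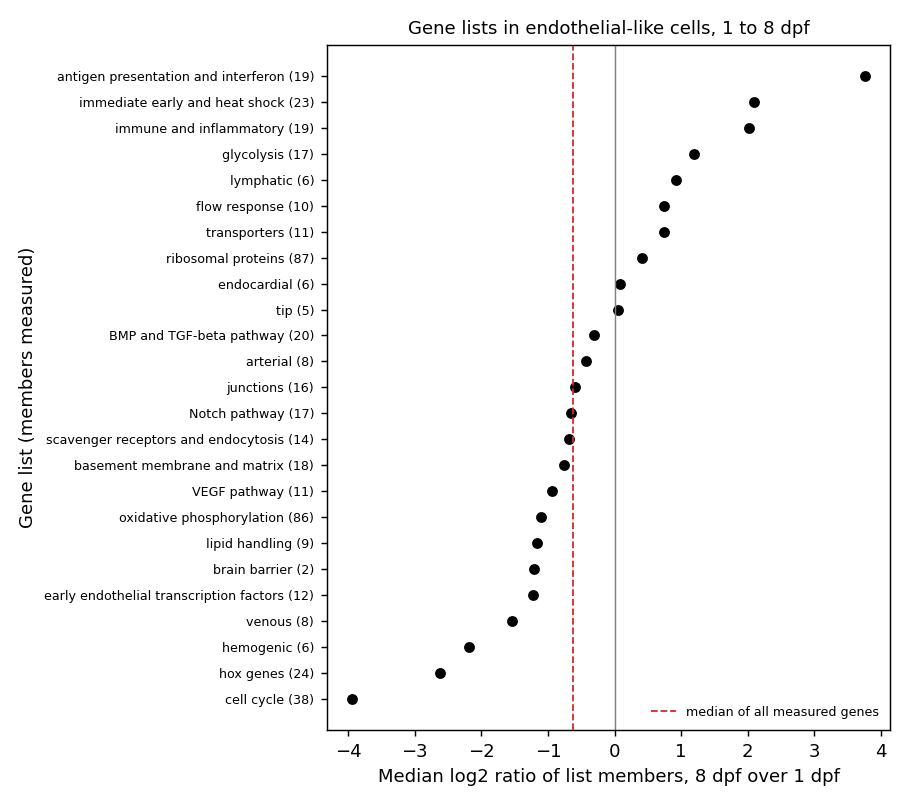
Median log2 ratio of each gene list in the endothelial-like class, 8 dpf over 1 dpf, with the median of all genes drawn for reference. The interferon list lay highest at 3.76 and the cell cycle list lowest at -3.94. With TMM, which is not drawn, the arterial, BMP and TGF-beta and junction medians turned from -0.43, -0.31 and -0.59 to 0.18, 0.26 and 0.01.

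From 1 to 2 dpf the largest ratios in the endothelial-like class belonged to few and partly non-endothelial genes, read from 131 cells at 2 dpf. The iron carrier gene tfa, a liver marker, had 125 (105 to 149) CPM at 2 dpf and no UMI at 1 dpf, at least 192-fold higher. The secreted-protein gene cbln11 was at least 128-fold higher. The apolipoprotein gene apoa2, also a liver marker, had a log2 ratio of 6.24 (6.197 to 14.03) with 1 UMI at 1 dpf. Cldn11a was at least 87.2-fold higher, and the co-chaperone gene DNAJA4 was at 5.84 (5.54 to 8.83). Lower at 2 dpf was id1, a target of BMP signalling, with 7209.9 (7132 to 7288) CPM at 1 dpf and 203 (177 to 232) at 2 dpf, a ratio of -5.14 (-5.35 to -4.95), where free RNA held 1393 and 496 CPM. So were apoc1 at -6.38 (-12.71 to -4.93) and the ventral homeobox gene vox at -4.31 (-10.62 to -2.81), each with 1 UMI at 2 dpf. Vwde and clul1 had no UMI at 2 dpf and were at least 8.79-fold and 7.11-fold lower by the floor of 3 counts. The ratio of apoa2 was 0 and that of apoc1 1.001 without subclusters led by genes of other classes, a set that lacks subcluster 9, itself led by apoc1. That of cldn11a was 0 with cells thinned to 1000 UMIs, and that of vwde 0.62 when any cell with UMIs of 2 of 10 endothelial genes was taken.

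All genes had a median of 0.24 from 1 to 2 dpf, -0.21 with TMM. Against it, interferon genes (7 of 9 at least 2-fold higher, median 1.74, 1.51 relative) and immune genes (6 of 12, 1.06, 0.82 relative) were higher at 2 dpf. Isg15 was at 2.49 (2.08 to 3.08) and nfkbiaa at 2.86 (2.57 to 3.27). Flow response genes were higher in 5 of 10 (1.01, 0.78 relative). Cyp1b1 was at 3.82 (3.47 to 4.43) and the endothelin gene edn1 at 1.87 (1.47 to 2.37) against klf6a at -1.32 (-1.45 to -1.20). Endocardial markers had a median of 0.94 (0.71 relative), with gata5 at 4.14 (3.70 to 5.31) and hand2 at 2.95 (2.53 to 3.67). Hemogenic genes were lower, 3 of 5 by 2-fold or more (-1.71, -1.95 relative), with lmo2 at -2.22 (-2.49 to -1.98) and tal1 at -1.71 (-2.23 to -1.28). Their median turned to 0.36 when any cell with 2 of 10 endothelial genes was taken. Cell cycle genes were lower in 11 of 39 (-0.54, -0.78 relative), with mcm5 at -2.43 (-3.71 to -1.61). In the library where they were higher, 24 of the 39 cell cycle genes, 5 of the 12 immune genes and 38 of the 83 oxidative phosphorylation genes were no higher than in free RNA. The stress genes hsp70.2 and hsp70.3 were at 3.78 (3.53 to 4.14) and 3.73 (3.53 to 3.99). Free RNA held 67.2 against 840.1 CPM and 94.3 against 1763 CPM of them. The brain barrier, tip, Notch, BMP and TGF-beta, matrix, scavenger, transporter and oxidative phosphorylation medians were 0.14, 0.28, 0.09, 0.06, 0.10, 0.36, 0.24 and 0.19 and turned to -0.28, -0.16, -0.38, -0.34, -0.37, -0.10, -0.23 and -0.28 with TMM.

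From 2 to 4 dpf, id1 was among the genes with the highest ratios in the endothelial-like class. It stood at 203 (177 to 232) CPM at 2 dpf and 5619 (5556 to 5684) at 4 dpf, a ratio of 4.78 (4.59 to 4.99), with 3457 CPM in free RNA at 4 dpf. The AP-1 gene fosb had 13.3 and 617 CPM, a ratio of 5.43 (4.79 to 6.41). Nppb, for a natriuretic peptide, had 58.3 (52.0 to 65.2) CPM and no UMI at 2 dpf, at least 20.5-fold higher. The potassium channel subunit gene kcne4 was at 5.52 (4.26 to 9.17) with 2 UMIs at 2 dpf, and the chemokine gene ccl38a.5 was at least 9.70-fold higher. The lectin gene itln3 and cbln11 had no UMI at 4 dpf and were at least 178-fold and 148-fold lower. Hist1h4l was at -5.08 (-5.49 to -4.84), and the linker histone genes histh1l and h1f0 were at -4.07 (-4.19 to -3.97) and -3.90 (-4.22 to -3.68). Epidermis-like and neural-like cells also had less hist1h4l and histh1l at both 4 and 8 dpf than at both 1 and 2 dpf. Most 4 dpf cells were of clusters 2, 8 and 12, as above. The ratio of itln3 was lost under 4 alternatives, among them the set without subclusters led by genes of other classes, where it was 0.

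The median of all genes from 2 to 4 dpf was -0.50, and 0.22 with TMM. Immediate early and heat shock genes were at least 2-fold higher in 19 of 23 (1.81, 2.31 relative, above all random lists), with egr1 at 3.58 (2.96 to 4.48). In contrast, hspa5, a chaperone of the endoplasmic reticulum, was at -2.12 (-2.22 to -2.04), with 1862 and 342 CPM in free RNA. Epidermis-like and neural-like cells also had more egr1 at both 4 and 8 dpf than at both 1 and 2 dpf, by at least 4.23-fold. Glycolysis genes were higher in 8 of 17 and lower in 2 (0.93, 1.43 relative, above all random lists), with eno1a at 3.23 (2.66 to 4.01). Immune genes were higher in 9 of 19 (0.78, 1.28 relative), with socs3a at 3.21 (2.94 to 3.53) and 10 of the 19 no higher than in free RNA, as were BMP and TGF-beta genes in 7 of 19 (0.37, 0.87 relative), with id2b at 3.67 (3.08 to 4.50). Hox genes were lower in 11 of 12 (-2.75, -2.25 relative, below all random lists), with hoxb3a at -2.99 (-4.08 to -2.49). So were cell cycle genes in 22 of 36 (-1.27, -0.77 relative), with mki67 at -2.28 (-2.79 to -1.91) and 26 of the 36 no higher at 2 dpf than in free RNA, and venous markers in 5 of 8 (-1.30, -0.80 relative), with stab2 at -2.75 (-3.09 to -2.49). Of the arterial list, the claudin gene cldn5b was at 1.17 (1.08 to 1.26) and the Notch ligand gene dll4 at 0.66 (0.51 to 0.82). Cldn5b did not mark arterial-like cells alone. Over all stages it had 3100 and 1750 CPM in arterial-like subclusters 3 and 13, and 611, 2924 and 2150 in lymphatic-like subclusters 6, 11 and 16. Unnamed subcluster 14 had 3199. The arterial, early transcription factor, Notch, VEGF, junction, interferon and oxidative phosphorylation medians were -0.13, -0.20, -0.55, -0.62, -0.38, -0.17 and -0.46 and turned to 0.62, 0.55, 0.19, 0.02, 0.36, 0.54 and 0.31 with TMM.

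From 4 to 8 dpf interferon genes stood out. Irf7, a regulator of interferon production, had 6.58 and 225 CPM, a ratio of 4.90 (4.61 to 5.63). Rsad2 had 4.89 and 242 CPM, or 5.36 (5.07 to 6.25), and ociad2 5.83 and 321 CPM, or 5.56 (5.27 to 6.35). Mxb, for an antiviral GTPase, and CABZ01073795.1 had no UMI at 4 dpf and were at least 65.1-fold and 185-fold higher. Lower at 8 dpf were the myoglobin gene mb at -4.10 (-4.48 to -3.87), klf11a at -4.37 (-7.34 to -4.07) and p4ha1b, for a collagen prolyl hydroxylase, at -4.04 (-5.76 to -3.67). So were the matricellular gene cyr61l1 at -4.02 (-6.58 to -3.69) and the cytochrome gene cyp1c1 at -3.97 (-4.46 to -3.71). Clusters 2, 8 and 12 supplied 458, 447 and 258 cells at 4 dpf and 240, 75 and 169 at 8 dpf. Mb and cyp1c1 lead subclusters drawn from the 4 dpf library. Irf7, rsad2, ociad2 and CABZ01073795.1 are among the leading genes of subcluster 5, with 138 of its 139 cells at 8 dpf.

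The median of all genes from 4 to 8 dpf was -0.42, and -0.14 with TMM. Of 19 antigen presentation and interferon genes 15 were at least 2-fold higher and 0 lower (3.51, 3.93 relative, 3.56 with members at 0 at their bound, above all random lists). The lowest ratios were those of irf9 at -0.94 (-1.40 to -0.58) and stat1a at -0.17 (-0.32 to -0.03), the latter turning positive with TMM. Lymphatic markers had a median of 0.48 (0.89 relative), with angpt2a at 2.60 (2.40 to 2.89) and lyve1a at 1.51 (1.42 to 1.61). Cell cycle genes were at least 2-fold lower in 28 of 33 (-2.19, -1.77 relative, below all random lists), with cdk1 at -3.89 (-6.15 to -3.53), and 28 of the 33 were no higher at 4 dpf than in free RNA. Oxidative phosphorylation genes were lower in 32 of 85 (-0.89, -0.47 relative), although 79 of the 85 were no higher in the class than in free RNA. Matrix genes were lower in 9 of 18 (-1.05, -0.63 relative), 8 of them no higher than in free RNA. The fibrillar collagen genes col1a2 and col1a1a were at -2.95 (-3.36 to -2.69) and -2.43 (-2.91 to -2.13), against 1.08 (0.81 to 1.43) and 2.06 (1.79 to 2.45) for the basement membrane collagen genes col4a1 and col4a2. BMP and TGF-beta genes were lower in 9 of 20 (-0.97, -0.56 relative). Endocardial markers had a median of -0.94 (-0.52 relative), with gata5 at -2.88 (-4.10 to -2.47) and hand2 at -2.52 (-2.86 to -2.29). The claudin genes went opposite ways, cldn5b at -1.48 (-1.53 to -1.43) and cldn5a at 1.78 (1.52 to 2.15). The junction, flow, immediate early and transporter medians were -0.12, -0.16, -0.25 and -0.09 and turned to 0.20, 0.16, 0.06 and 0.22 with TMM.

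The share of endothelial-like cells with transcripts of mitotic genes was lower at each later stage. With each cell thinned to 1000 UMIs, 16.7% (13.4 to 20.6) of 442 cells at 1 dpf, 11.5% (6.55 to 18.2) of 131 at 2 dpf and 4.11% (3.05 to 5.42) of 1167 at 4 dpf had such transcripts. The measure was a UMI of at least 2 of 12 cell cycle genes, among them mki67, top2a and cdk1. At 8 dpf 0 of 484 cells did, which allows a share of up to 0.759%. The unthinned shares were 52.04%, 29.8%, 11.1% and 0.620%. Without subclusters led by genes of other classes the thinned share at 1 dpf was 35.2%. That set kept 165 of the 442 cells, 99 of them in subcluster 10, itself led by mitotic genes such as plk1 and aurkb. The higher share thus follows from which cells were kept. Free RNA carried cell cycle transcripts at 1, 2 and 4 dpf, so that how far these shares count dividing cells is open.

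Clustered alone, the 2224 endothelial-like cells formed 18 subclusters, 12 of them unnamed, and most came from a single library. Arterial-like subcluster 13, led by her4.1, her12, her2, her15.1 and csrp2, held 66 of its 68 cells at 1 dpf. Arterial-like subcluster 3, led by zgc:112332, six3a, cyr61l1, cyp1c1 and ncam3, came from the 4 dpf library alone with 153 cells. Its name rests on 3 of 12 markers, none of them among its 10 leading genes. Endocardial-like subcluster 0, led by mb, nppb, kcne4, BX901920.1 and epoa, held 281 of 283 cells at 4 dpf. Unnamed subcluster 2, led by anxa2a, thbs1a, hand2, alcama and cd151 with 171 of 187 cells at 4 dpf, had more of the endocardial markers hand2 and gata5, 459 against 251 and 79.9 against 64.5 CPM. Unnamed subcluster 17, with 44 of 46 cells at 1 dpf, had 90.2 of hand2 and 83.9 of gata5. Among all cells, clusters 8 and 31 were named by the endocardial list, with 4 and 6 of its 6 markers. They held 75 cells at 8 dpf and 43 at 1 dpf, so endocardial markers were not confined to 4 dpf. Lymphatic-like cells fell in subcluster 6, with 126 cells of the 8 dpf library led by CR318588.1, mrc1b, angpt2a, si:ch211-152c2.3 and zgc:123068. Others fell in subclusters 11 and 16, with 99 and 46 cells at 4 dpf. Subcluster 16 was led by osr2, selenop, slc7a7, si:ch211-214p13.9 and gng10, with 1718 CPM of lyve1b against 279 in subcluster 11. In the lymphatic-like subclusters cdh5 stood at 4.90, 19.2 and 25.7 CPM, against 483 and 255 in the arterial-like and 206 in the endocardial-like ones.

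Among the unnamed subclusters, number 5 held 138 of its 139 cells at 8 dpf and was led by the interferon genes irf7, isg15 and rsad2 together with ociad2 and CABZ01073795.1. Subcluster 8 held 114 cells, all from the 2 dpf library, and was led by hsp90b1, pdia4, bbc3, tcf15 and serpinh1b. Of these, hsp90b1 and pdia4 encode proteins that fold others in the endoplasmic reticulum. Subcluster 4, with 115 cells at 4 dpf and 29 at 8 dpf, was led by aoc2 and by the liver genes apoa1b, apoa2, tfa and fabp10a. It also had endothelial and arterial markers, with 319 CPM of cdh5, 387 of kdrl, 1319 of dll4 and 470 of cxcr4a. Arterial-like subcluster 3 had 255, 316, 1297 and 314, but more cldn5b, 3100 against 2425. Subcluster 9, with 108 cells at 1 dpf, was led by apoc1, dnase1l4.1, apoeb, hoxa11b and ap1s3b, and subcluster 10, with 99 of 107 cells at 1 dpf, was led by hist1h4l, plk1, ube2c, aurkb and si:ch211-69g19.2. Sizes of subtypes are not compared between stages, because the arterial-like share at 1 dpf, 14.9%, was 0 under 7 alternatives, another random seed of the clustering among them. The share of lymphatic-like cells at 8 dpf, 27.1% (23.2 to 31.3), stayed within its interval under all alternatives run on it.

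Markers of other tissues were present in the endothelial-like class mostly below their level in free RNA. The 17 endothelial markers summed to 5338, 5283, 3842 and 2750.2 CPM at the 4 stages, against 327, 323, 1313 and 331 in free RNA. Erythroid genes summed to 21604, 7374, 195 and 746 CPM, against 289766, 58222.5, 1809 and 8235 in free RNA. Epidermis genes summed to 724, 874, 1572 and 1126 against 5186, 6394, 16092 and 20039. Liver genes were above free RNA at 2 dpf, with 228 against 31.1 CPM, of which apoa2 and tfa made up 91.2 and 125. Without subclusters led by genes of other classes, which leaves 126 of the 131 cells there, the ratio of apoa2 from 1 to 2 dpf was 0. At 4 and 8 dpf liver genes were below free RNA, where the sums were 236 against 2346 and 85.4 against 373. Arterial, venous, lymphatic, brain barrier, endocardial and tip lists, which name endothelial subtypes, were above free RNA at all 4 stages. In this order they summed to 2368, 1096, 245, 126, 1224 and 1732 CPM at 1 dpf and 1719, 249.6, 1011, 81.99, 819.7 and 477 at 8 dpf.

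The other lists were read at 8 dpf. They summed to 131 CPM for blood progenitors (free RNA 107), 9.35 for macrophages (183), 152 for neutrophils (3753), and 42.9 for thrombocytes (114). The sum was 114 for neural cells (76.2) and 4.25 for neural crest and pigment cells (42.2). Cartilage and pharyngeal arch genes summed to 5.52 CPM (42.2 in free RNA), mesenchyme genes to 76.04 (265), mural genes to 44.8 (172), skeletal muscle genes to 97.3 (2546) and cardiomyocyte genes to 6.58 (11.03). Exocrine pancreas genes summed to 345 CPM (11625), gut genes to 3.19 (58.4) and eye genes to 5.52 (104). Blood progenitor and neural genes were the only lists of other tissues above free RNA at 8 dpf, and early endothelial cells also express lmo2 and tal1 of the former. At 1 dpf the blood progenitor, mural, eye and neural crest lists were above free RNA, with 776 against 268, 78.2 against 30.9, 16.8 against 4.88 and 14.2 against 10.8 CPM. At 2 dpf so was the cardiomyocyte list, with 28.5 against 5.30 CPM.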

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

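All tests in this part were chosen only after the results they concern had been seen. Endothelial transcripts were present in barcodes that enter no comparison because their UMIs fall short of the minimum for a cell. From 500 UMIs up to that minimum, 284 (252 to 319) of 23343 barcodes at 1 dpf had UMIs of 3 or more of 10 endothelial genes such as cdh5, kdrl and tie1. The counts were 95 (76.9 to 116) of 1075 at 2 dpf, 285 (253 to 320.1) of 1863 at 4 dpf and 420 (381 to 462) of 3814 at 8 dpf. Free RNA at the same depth, with a profile from barcodes beyond the 10000 largest, gives 1.002, 2.48, 51.3 and 7.27, and the excess over these numbers is what drew attention to them. What kind of droplet they are was not tested, and the shares with a minimum of 500 UMIs, which take them in, are given with the other alternatives.

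GFP transcripts were more abundant at 2 dpf in arch-like cells, led by genes such as grem2b, dlx2a and col2a1a, than in the endothelial-like class (953 against 468 CPM). Free RNA as the whole source is argued against by a level 3.45 and 3.66 times that in the 2 profiles of droplets without a cell. Doublets with endothelial cells would bring cdh5 along with GFP, but the class had 0.00915 of the endothelial cdh5 level and 2.04 of the endothelial GFP level, a ratio of 0.00450. Fli1a stood at 139.8 CPM in the class against 1.23 in erythroid-like and 0 in neural-like cells, 113 times the higher of them, but at 2 dpf fli1a did not mark GFP across classes: blood-progenitor-like cells had 131 CPM of fli1a and 77.9 of GFP, 0.299 (0.223 to 0.373) times free RNA, and neutrophil-like cells 72.1 and 15.4. At 1 dpf the named classes with most fli1a, endothelial-like, arch-like and blood-progenitor-like (21 cells), had 365, 72.2 and 71.9 CPM of it. These classes had 4403, 807 and 625 CPM of GFP, against 264 in free RNA. Of the arch-like cells at 2 dpf, 83.8% had a UMI of GFP, 54.3% of fli1a and 6.73% of kdrl. Kdrl stood at 11.6 CPM in them, against 10.1 in free RNA. An active reporter in arch-like cells therefore stays open, and which promoter would drive it was not tested.

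Among endothelial-like cells at 1 dpf, 114 of 442 (25.8%) had no GFP UMI. If all had the GFP level of the others, their depth would leave 0.965% without one, which argues against too few UMIs as the whole cause. Cells of another type would lack cdh5, yet cells without a GFP UMI had 0.997 (0.903 to 1.099) times the cdh5 level of cells with one at 1 dpf, and 0.657 (0.567 to 0.759) times at 8 dpf, both intervals lying above the bound of 0.5 that was set. The lower ratio at 8 dpf leaves open a minority of cells of another type or more lymphatic-like cells, of which subcluster 6, with 126 cells, had 4.90 CPM of cdh5 and 168 of GFP. No biological explanation was tested, and an uneven activity of the reporter among endothelial cells or a spread of the sort stays open.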

How the results depend on the processing

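The first naming rule, Leiden seed 1, clustering without the 2 dpf library, the second free RNA profile and the class without mixed subclusters (those led by genes of other classes) were chosen after seeing the data, and the other alternatives before. The 5 lists, 5 shares of other classes and 5 shares of subtypes followed in detail were also picked after their values had been seen. No paired analysis was possible because each stage has 1 library and the labels link none. Depth limits what can be read: the 131 endothelial-like cells at 2 dpf and the median of 3816 UMIs per such cell at 4 dpf leave many genes with few counts. Where an alternative below does not give the reason by its own construction, the cause was not tested.

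With a minimum of 500 UMIs, the endothelial-like share was 10.5%, 9.88%, 58.6% and 18.5% at 1, 2, 4 and 8 dpf, the erythroid-like 47.8% and 18.7% at 1 and 2 dpf, the arch-like 45.1% at 2 dpf, and the epidermis-like 19.7% and blood-progenitor-like 9.85% at 8 dpf. The endocardial-like share was 17.2% at 4 dpf and the arterial-like 0% at 1 and 10.9% at 4 dpf. With 2000 UMIs, the endothelial-like share was 17.3% at 1 and 16.5% at 8 dpf, the epidermis-like 19.2% and blood-progenitor-like 11.1% at 8 dpf, and the arterial-like 0% at 1 and 26.6% at 4 dpf. With the per-cell gate of 2 of 10 genes, the endothelial-like share was 17.5%, 16.9% and 15.6% at 1, 2 and 8 dpf. That gate reversed the hemogenic median from 1 to 2 dpf (0.36), the Notch median from 2 to 4 dpf (0.11), apoa2 (-0.60) and vwde (0.62) from 1 to 2 dpf and itln3 (0.23) from 2 to 4 dpf.

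The arterial-like share at 1 dpf, 14.9%, depends on which cells are clustered and how. It was 0% with mitochondrial limits of 5% and 20%, without doublet removal, at resolution 0.5 and with Leiden seed 1. At 4 dpf the arterial-like share was 29.2% with the limit of 20%, 18.4% without doublet removal, 18.4% at resolution 2 and 18.5% with seed 1, and the endocardial-like 39.1% at resolution 0.5, 29.3% at resolution 2 and 29.5% with seed 1. Resolution 2 also gave 31.4% arch-like cells at 2 dpf and 4.92% blood-progenitor-like cells at 8 dpf. With each library clustered alone, these were 17.1% and 6.75%, the epidermis-like share at 8 dpf 15.9%, apoa2 from 1 to 2 dpf -0.28 and itln3 from 2 to 4 dpf 0. The first naming rule gave 25.2% arch-like cells at 2 dpf, 4.85% epidermis-like at 8 dpf, and at 4 dpf 0% endocardial-like, 0% arterial-like and 3.94% lymphatic-like cells.

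Thinning to 2000 UMIs, which leaves more transcripts per cell to detect, put the share of cycling cells at 28.3%, 19.8% and 7.66% at 1, 2 and 4 dpf. Thinning to 1000 UMIs gave medians from 1 to 8 dpf of -4.96 for cell cycle and -3.43 for hox genes, and 0.45 for Notch from 2 to 4 dpf, and cldn11a from 1 to 2 dpf came to a log2 ratio of 0. A pseudocount of 10 CPM, which shrinks ratios of low genes by construction, gave medians of -2.102 for cell cycle, 1.39 for interferon and -0.95 for hox genes from 1 to 8 dpf. Without cells with UMIs of 2 of the 12 cell cycle genes, the cell cycle median was -2.84, apoa2 -0.60 and itln3 0. Members with 1 or more UMIs brought the hox median to -1.66. TMM factors reversed junctions from 1 to 8 dpf (0.0139), oxidative phosphorylation from 1 to 2 (-0.28) and 2 to 4 dpf (0.31) and Notch from 2 to 4 dpf (0.19). Without the 6 subclusters led by genes of other classes, 165, 126, 858 and 317 cells were kept. At 1 dpf 35.2% were cycling, where 99 of the 165 cells kept were of subcluster 10, itself led by mitotic genes. The cell cycle median, to which the same cells contribute, was -4.41. The ratios of apoa2, apoc1 and itln3 were 0, 1.001 and 0.

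Cell cycle, hox, interferon, glycolysis and immediate early medians from 1 to 8 dpf kept their sign under all alternatives run. Of their 110 values, 102 stayed within the 95% range that the order of the list's members gives its median and 8, those above, moved out of it. For the other lists, 1973 of 2038 values stayed within it, 58 moved and 7 reversed. Counting medians near 0, whose range takes in both signs, 141 of the 2038 had another sign than reported. For named genes it was 656 of 1060, with 393 moved and 11 reversed. Of values for shares, 38 of 47 stayed within the first interval for endothelial-like cells, 39 of 53 for other classes, 25 of 45 for subtypes and 39 of 43 for cycling cells. The lymphatic-like share at 8 dpf, 27.1%, stayed in its interval under all alternatives run on it.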

Other observations

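Of the tests in this part, those of single genes across classes, of pairs of stages and of free RNA were chosen only after the result was seen, while those of the subcluster mix and the whole library were set before; the genes named here were also chosen after their values were seen. Among the named classes with at least 30 cells at 8 dpf, the antiviral genes isg15 and rsad2 lay above their level in free RNA in the endothelial-like class alone. Isg15 stood at 829 CPM in endothelial-like cells, 222 in macrophage-like, 158 in mural-like and 56.5 in neural-like cells, with 231 in free RNA. Within the endothelial-like class it was uneven. The subclusters with most 8 dpf cells, 5, 6, 1 and 15, held 2338, 423, 227 and 55.6 CPM over their cells of all stages. The class level therefore does not hold for each of its subclusters. At 4 dpf isg15 had 48.2 CPM in endothelial-like, 70.6 in macrophage-like and 4.98 in neural-like cells. Rsad2 at 8 dpf had 242 CPM in endothelial-like, 28.3 in mesenchyme-like, 18.6 in mural-like and 5.87 in macrophage-like cells and 28.5 in free RNA. B2m, the light chain of antigen-presenting molecules, was as high in blood-progenitor-like cells, 294 CPM, as in endothelial-like cells, 287, with 102 in free RNA.

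The low cell cycle and hox values at 8 dpf were shared by other classes. From 1 to 8 dpf the cell cycle median was -4.65 in epidermis-like, -2.94 in neural-like, -1.60 in erythroid-like and -1.52 in macrophage-like cells, and the hox median -2.40 in epidermis-like and -2.50 in neural-like cells. Glycolysis genes, at 1.19 in the endothelial-like class, had medians of -0.28, 0.14 and -0.67 in epidermis-like, neural-like and macrophage-like cells, and 1.56 in erythroid-like cells. Most erythroid-like cells at 8 dpf were of cluster 11, named by 5 of 13 markers, so both erythroid-like medians may compare unlike cells. At 2 dpf id1 was lower than at 1 dpf in other classes too, at 501 CPM in arch-like, 253 in epidermis-like and 239.5 in neural-like cells, against 2771, 2222 and 2504 at 1 dpf, and in free RNA, at 496 against 1393. The chaperone genes hspa5 and hsp90b1 were high at 2 dpf in arch-like cells, at 2849 and 1205 CPM, in neural-like cells, at 1982 and 719, and in free RNA, at 1862 and 675. At 1 dpf they had 404 and 99.2, 451 and 123, and 247 and 40.7 in the same order.

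A few genes parted the libraries in pairs alike in endothelial-like, epidermis-like and neural-like cells. With a fold of at least 2 and at least 20 CPM in all 3 classes, 23 genes were higher at both 1 and 2 dpf than at both 4 and 8 dpf, and 13 the other way. The first were led by the haemoglobin genes hbbe3 and hbae3, at 48106 and 52781 CPM in free RNA at 1 dpf, and the others by prss59.2, si:dkey-33c14.3, ctrb1 and prss1, of which the proteases prss59.2, ctrb1 and prss1 had 2893, 2548 and 2664 CPM in free RNA at 8 dpf. Hist1h4l and histh1l were also among the first, by at least 8.70-fold and 7.36-fold, and egr1 among the others, by at least 4.23-fold. For 2 and 4 dpf against 1 and 8 dpf there were 5, NDUFA13, uqcrb, COX7A2 (1 of many), mt-nd3 and rpl26, and for 1 and 4 dpf 1, kctd12.2, with 0 for the remaining pairs. Rpl26 stood at 8.06, 591, 796 and 210.3 CPM in endothelial-like cells and 12.5, 589, 633 and 179 in free RNA. The check was set after rpl26, uqcrb and ndufb11 had been seen. It was first meant for 4 classes and a 4-fold limit and was changed before it was run, with erythroid-like cells left out after their rpl26 had been seen.

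Antigen presentation and interferon genes were higher in the endothelial-like class at 8 than at 4 dpf, with a median log2 ratio of 3.51. Free RNA as their source is argued against, since 2 of 19 members stood at or below their level in droplets without a cell. A change in the mix of subclusters stays open, although 4 of 5 subclusters had a median at or above the bound of 1 that was set, at 1.60, 2.08, 2.52 and 4.29 (the last from 4 members and 16 cells at 4 dpf) against 0.171 in the other. These medians decide nothing: subclusters were made from the same expression, and subcluster 5, led by irf7, isg15 and rsad2 and with 138 of 139 cells from 8 dpf, drops out of them. A difference of the whole 8 dpf library cannot be told apart from one of these cells either, since in 7 other classes the medians ran from 0.696 to 1.46, 5 of them at or above the same bound. Age, which is the difference between the libraries, may be the cause but is untested with 1 library per stage.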
